A study of Mus musculus with 6 samples.

How the data were processed

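Total RNA from RAW264.7 cells was sequenced in 6 libraries, 3 from cells given PBS and 3 from cells given Ti particles, and each sample was assigned to its group by its labels. The deposited values are estimated counts per transcript, whole numbers in 187351 rows for each library. The reads were processed with HISAT2 and StringTie, per the submitters' processing notes, which also list the genome build mm9. Versions and the counting tool are not given in the sources used here. Of the rows, 141862 carry Ensembl transcript identifiers and match one for one the 141862 transcripts of GENCODE vM21, an annotation of GRCm38. Gene names and coordinates were therefore taken from GENCODE vM21 and are on GRCm38, although the notes list another build. The other 45489 rows are assembled transcripts without a gene or position.

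The deposited totals, 456595115 to 773215120 per library, are far above the rescaled ones, and low values rose with genomic span. Over 9 bins of the ratio of genomic span to exon length, the lower quartile of nonzero values rose from 3 to 334 as the median ratio rose from 1 to 144 (slope on log scales 0.872). The deposited estimated count of each annotated transcript was therefore multiplied by exon length over genomic span, summed per gene and rounded to whole numbers. This was decided from the values before any test was run. Among protein-coding transcripts the slope of the value on span was 0.716 before this step and -0.284 after it, so the correction is approximate. The step lowers this slope by a fixed amount, so the second value follows from the first and is not a separate check. Assembled transcripts, 36.9% to 51.2% of the deposited totals, were kept out of gene sums and library sizes and tested separately. Because the unit was neither a plain count nor FPKM, the test used was the one planned for counts, applied to rescaled estimated counts.

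Genes were tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg at 0.05. Of 55536 genes 15376 were tested. CPM values are counts over TMM-scaled library sizes. The detection floor, the bounds for on/off transcripts and the marker comparison used unscaled library totals instead. The standard error of a log2 fold change is its size divided by the square root of the F statistic. For genes with few counts in a group, such as Ccl7 and Mrps18c, it can be smaller than counting error alone. Gene lists, 35 fixed before the data were examined, were tested with camera (limma 3.58.1, preset correlation 0.01) on log-CPM with a prior count of 2 where at least 3 members were measured, which held for 31. They were tested again with an estimated correlation and with fry, and the p-values of each were adjusted over lists. DESeq2 1.42.0 was run as an alternative. Tables and plots were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

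The rule for named genes, also fixed before the data were examined, took up to 10 genes of each direction past the threshold with separated groups and a mean of at least 5 CPM, up to 4 members of each list with the smallest p, 5 non-coding genes of each direction past the threshold with a mean of at least 1 CPM, and 12 genes in any case (Tnf, Il1b, Il6, Il1rn, Nos2, Ptgs2, Ccl2, Nfkbia, Hmox1, Acp5, Mmp9 and Nlrp3). It gave 135 tested genes, of which 55 are named besides Malat1. Which of them to name was chosen after their values were seen, mostly members past the adjustment over their list.

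No 2 libraries agreed within sampling noise, so all 6 were kept as separate samples. Same-numbered libraries of the 2 groups deviated together from their group means, with correlations across genes of 0.110, 0.144 and 0.266 for numbers 1, 2 and 3, against -0.170 to 0.0402 for other pairs. By the rule that every pair exceeds 0.1, the numbers were taken to pair the samples. The pairing comes from the data and not from the labels. The fit without the block had been fixed as the main one. Blocked values are given where they change a gene call over all genes or a list call. Calls adjusted over a list alone come from the fit without the block and were not repeated with it.

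The tests were also run on simulated data. Counts for 15376 genes were drawn 3 times from the observed means, dispersions and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. For Ti against control at this size, edgeR recovered 2.33% of the 2-fold and 52.7% of the 4-fold changes, and 10.8% of its calls were false. DESeq2 recovered 28.0% and 87.7%, and 39.3% of its calls were false. The chemokine list, raised by 1 on the log2 scale, was called by camera in 3 of 3 simulations. Genes were drawn independently, so the simulations do not test how often lists are called falsely.

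Alternatives planned before the data were examined were no filter on low counts, a mean of at least 50 counts, DESeq2's size factors, DESeq2's test, voom with quality weights, the replicate block, leaving out each library, an estimated correlation and a minimum log2 fold change of 1. Those added after seeing the data were deposited values summed without rescaling, robust dispersions, both libraries numbered 3 left out, DESeq2 with the replicate block, and transcripts left out that were on (at least 20 CPM) in one library and off (at most 0.2 CPM) in another.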

Results

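RNA was profiled in RAW264.7 cells, a mouse macrophage line widely used to study inflammatory responses and osteoclast formation. There were 2 groups of 3 libraries each, cells given phosphate-buffered saline (PBS, the control) and cells given titanium (Ti) particles, the kind of debris that metal implants shed. The study set out to examine coding and non-coding RNA after exposure to the particles; dose and exposure time are not given in the sources used here. After rescaling, the annotated transcripts summed to 60242937, 41164142 and 42853939 estimated counts in control replicates 1, 2 and 3 and to 46276680, 37686020 and 48543436 in Ti replicates 1, 2 and 3. A rescaled count of 3 in a library corresponded to between 0.0498 and 0.0796 CPM (normalised counts), here over library totals without TMM scaling. This was taken as the floor below which a gene was not detectable, for counting error only. A rescaled count is not a number of reads, so the floor is approximate. All replicates came from one cell line, and the labels do not say that they were separate cultures, so p-values measure the spread between these samples, which may be technical.

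The comparison of Ti particles with PBS asked which genes and gene groups differed after exposure. Inflammatory mediators were higher with the particles as groups: 12 of 13 measured chemokines, 23 of 24 NF-kB target genes and 9 of 11 proinflammatory cytokines had positive fold changes. These 3 lists passed camera with a preset correlation, and none of them did with an estimated one (adjusted p = 0.127, 0.235 and 0.265 with an estimated correlation). Tnf, a central proinflammatory cytokine, averaged 126 ± 11.2 CPM in control and 272 ± 51.4 CPM with Ti (mean ± SD, n = 3 per group), a log2 fold change of 1.11 ± 0.16 (SE). Nos2, the inducible nitric oxide synthase, averaged 0.911 ± 0.273 and 13.7 ± 7.54 CPM, a log2 fold change of 3.90 ± 0.50. Gene by gene, 4 of 15376 tested genes passed an adjusted p of 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg), 2 higher and 2 lower, and none of these is an inflammatory mediator by the lists used here.

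The 2 genes that rose were Mrps18c and Myo1d. Myo1d (ENSMUSG00000035441, GRCm38 chromosome 11, 80482126 to 80780025, minus strand), an unconventional class I myosin, averaged 147 ± 7.88 CPM in control and 423 ± 42.5 CPM with Ti (n = 3 per group). Its log2 fold change was 1.53 ± 0.11, with an edgeR adjusted p of 0.0337. Mrps18c (ENSMUSG00000016833, chromosome 5, 100798627 to 100804471, plus strand), which encodes a protein of the mitochondrial ribosome, averaged 0.203 ± 0.0140 CPM in control and 28.0 ± 3.72 CPM with Ti, a log2 fold change of 7.08 ± 0.21 and an edgeR adjusted p of 0.000556. The 2 genes that fell were Inpp5b and AC133103.1. Inpp5b (ENSMUSG00000028894, chromosome 4, 124741850 to 124801511, plus strand), an inositol polyphosphate 5-phosphatase, averaged 42.0 ± 4.25 CPM in control and 6.72 ± 0.453 CPM with Ti, a log2 fold change of -2.64 ± 0.15 and an edgeR adjusted p of 0.0115. AC133103.1 (ENSMUSG00000079190, unplaced scaffold GL456211.1, 167446 to 196478, plus strand) averaged 6.92 ± 0.141 and 1.45 ± 0.0773 CPM, a log2 fold change of -2.25 ± 0.18 and an edgeR adjusted p of 0.0480; whether it shares reads with a near-identical copy was not analysed here. In each of these 4 genes the 3 libraries of one group lay on one side of the 3 of the other.

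The Mrps18c and Inpp5b values followed mainly 1 transcript each, which was near 0 in every library of one group and abundant in the other. Transcript ENSMUST00000016977 of Mrps18c was at 0.11 rescaled counts in each control library and at 1120, 1084 and 1046 in Ti replicates 1, 2 and 3. Transcript ENSMUST00000184454 of Inpp5b, annotated as a target of nonsense-mediated decay, was at 2481, 1495 and 1258 in the control libraries and at 0 in each Ti library. With transcripts of this on/off kind left out, an alternative chosen after seeing the data, the log2 fold change of Inpp5b was 0.026 and that of Mrps18c 3.96, which follows from how such transcripts are chosen. Then no gene passed (lowest edgeR adjusted p 0.0571), although Myo1d (1.52, unadjusted p 6.72e-06, from 6.58e-06) and AC133103.1 (-2.25) hardly changed, so their calls were lost through the adjustment over all genes. With the replicate number as a block, 0 genes rose and 0 fell (lowest edgeR adjusted p 0.0718), with log2 fold changes of 7.07 for Mrps18c, 1.52 for Myo1d, -2.64 for Inpp5b and -2.25 for AC133103.1. Without the block DESeq2 called 163 genes higher and 129 lower. Leaving out 1 library at a time gave 1 to 8 genes higher and 0 to 7 lower. Mrps18c passed each time, and Myo1d did not without any 1 of the control libraries or Ti replicate 1. Inpp5b did not pass without control replicate 1, control replicate 2 or Ti replicate 1. AC133103.1 did not in any of the 6 fits (edgeR adjusted p 0.0810 to 0.202), nor with no filter on low counts (0.0876).

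**Figure D1:**
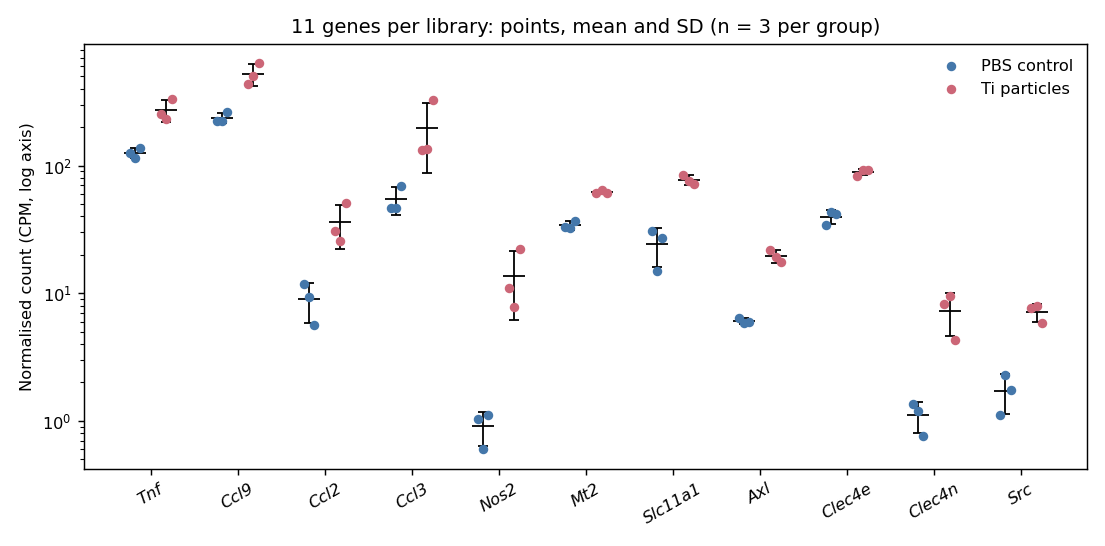
Normalised counts (CPM, log axis) of 11 genes in each of the 6 libraries, with the mean and SD of the 3 PBS control libraries (blue) and the 3 Ti libraries (red). Every Ti library lies above every control library for each of these genes. Tnf, for example, averaged 126 ± 11.2 CPM in control and 272 ± 51.4 CPM with Ti. The genes are among those named after their values were seen, so this separation may follow from how they were picked. Tnf did not pass over all genes tested (edgeR adjusted p 0.157).

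Among gene lists fixed before the data were examined, 13 of 31 tested passed an adjusted p of 0.05 in camera with a preset correlation of 0.01, 12 of them higher with Ti and 1 lower. None passed with a correlation estimated from the data. The estimate was below the preset value for some of these lists, such as metal handling (-0.065) and phagocytic receptors (-0.024). For those lists a higher correlation between members does not account for the lost call. With an estimated correlation camera also has far fewer degrees of freedom, set by the number of libraries and not of genes. Its adjusted p-values are therefore not a check of the correlation alone. By fry, which asks whether the members of a list move one way on balance, 3 lists passed: chemokines (adjusted p = 0.0151), phagocytic receptors (adjusted p = 0.0147) and metallothioneins with metal and iron handling genes (adjusted p = 0.00291). With the replicate number as a block none passed fry (adjusted p = 0.0522 for each of the 3). Of these fry calls the chemokine one was lost without control replicate 1, 2 or 3 or Ti replicate 2 (adjusted p = 0.455, 0.416, 0.0656 and 0.0618) and with no filter on low counts (0.103). The phagocytic receptor one was lost without control replicate 1 or Ti replicate 2 or 3 (adjusted p = 0.0776, 0.0581 and 0.0529). The metal-handling one was lost in none of the 6 fits with a library left out.

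**Figure D2:**
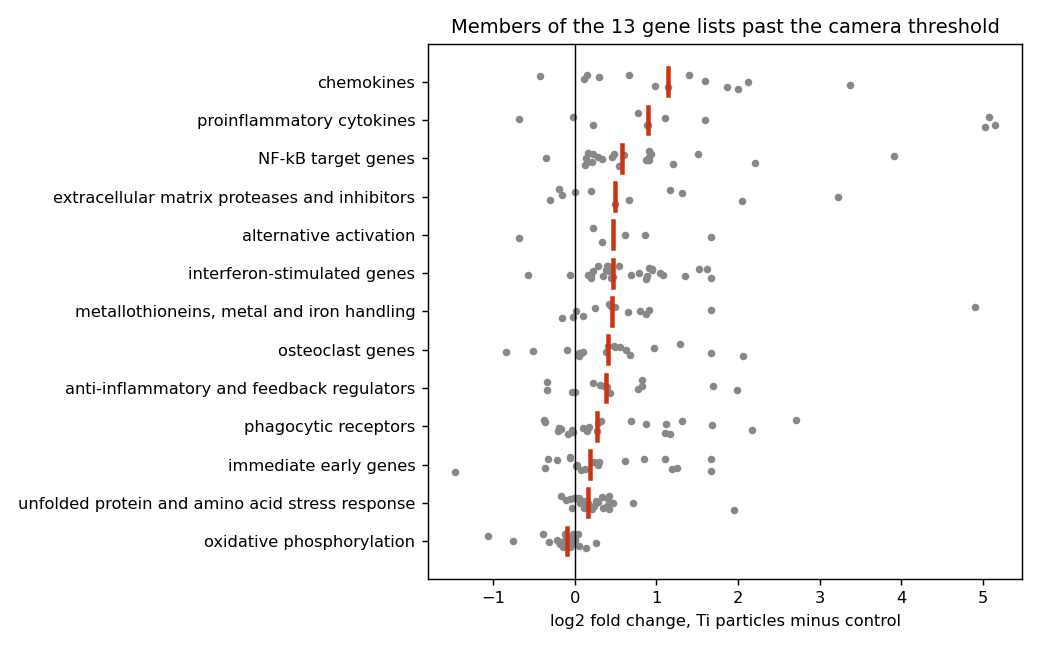
log2 fold changes (Ti particles minus control) of the members of the 13 lists that passed camera, each grey point a gene and each red bar the median of its list. Medians run from -0.10 for oxidative phosphorylation to 1.15 for chemokines.

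Chemokines, the secreted proteins that draw leukocytes, were the list with the largest median log2 fold change, 1.15 (camera adjusted p = 6.27e-08; adjusted p = 0.127 with an estimated correlation). Over all genes tested 0 members passed, and adjusted over the list alone 5 rose. Ccl9 averaged 236 ± 22.5 CPM in control and 524 ± 101 CPM with Ti (n = 3 per group), a log2 fold change of 1.15 ± 0.16. Ccl2, a monocyte chemoattractant, changed by 2.00 ± 0.38 on the log2 scale, Ccl3 by 1.87 ± 0.41 and Ccl7, at 2 to 4 counts in the control libraries and 17 to 40 in the Ti libraries, by 3.38 ± 0.44.

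Proinflammatory cytokines had a median log2 fold change of 0.90 (camera adjusted p = 3.84e-05; adjusted p = 0.265 with an estimated correlation). Over all genes tested 0 of 11 passed, and adjusted over the list alone 4 rose: Tnf, Csf3, Il1a and Il1b. The 3 last were scarce in control and uneven among the Ti libraries. Il1b, for example, stood at 27, 3 and 0 counts in the control libraries and at 102, 91 and 656 in Ti replicates 1, 2 and 3, a log2 fold change of 5.07 ± 1.36 that was 7.26 without control replicate 1, 3.69 without Ti replicate 3 and 3.15 without both libraries numbered 3. Csf3, which drives granulocyte production, stood at 8, 4 and 7 counts against 87, 69 and 447, and Il1a at 7, 0 and 2 against 36, 32 and 230. Il6 was at 0 counts in 5 libraries and at 2 in Ti replicate 3, so no difference was detectable at this depth.

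The 24 NF-kB target genes, all measured, had a median log2 fold change of 0.58 (camera adjusted p = 1.35e-09; adjusted p = 0.235 with an estimated correlation). Over all genes tested 0 passed, and adjusted over the list alone 4 rose: Nos2, Tnip1 by 0.91 ± 0.14, Marcksl1 by 0.94 ± 0.17 and Rel, an NF-kB subunit, by 0.55 ± 0.13 on the log2 scale. Nfkbia, which encodes an NF-kB inhibitor and is itself induced by NF-kB, had 0.34 ± 0.14 and Ptgs2, the inducible cyclooxygenase, 0.87 ± 0.46, and 0.49 without control replicate 3, and neither passed. Without Ti replicate 3 the median of the list was 0.29. Anti-inflammatory and feedback regulators had a median of 0.38 (camera adjusted p = 0.0181; adjusted p = 0.235 with an estimated correlation), with 11 of 14 members higher. Adjusted over the list alone 2 of them rose, Il1rn, the interleukin-1 receptor antagonist, by 1.69 ± 0.34 and Socs3, a cytokine signalling suppressor, by 1.99 ± 0.50, and 0 passed over all genes tested. That list lost its camera call without control replicate 2 (adjusted p = 0.0680) and without Ti replicate 3 (adjusted p = 0.109), where its median was 0.17.

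Receptors for particles and damaged cells were higher in part. Of 23 phagocytic receptor genes 15 were higher, with a median log2 fold change of 0.27 (camera adjusted p = 0.00157; adjusted p = 0.161 with an estimated correlation). Adjusted over the list alone 5 rose and 0 fell, and 0 passed over all genes tested. Axl, a receptor tyrosine kinase that binds apoptotic cells, averaged 6.08 ± 0.316 CPM in control and 19.5 ± 2.22 CPM with Ti (n = 3 per group), a log2 fold change of 1.69 ± 0.16. The C-type lectin receptors Clec4e, Clec4d and Clec4n had log2 fold changes of 1.17 ± 0.13, 0.87 ± 0.13 and 2.71 ± 0.39.

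Metal-handling genes were higher as a group. The 15 measured genes for metallothioneins, metal and iron handling had a median log2 fold change of 0.46, with 13 higher (camera adjusted p = 3.84e-05; adjusted p = 0.127 with an estimated correlation). Adjusted over the list alone 4 rose, and 0 passed over all genes tested. The metallothionein gene Mt2 averaged 34.0 ± 2.63 CPM in control and 62.2 ± 2.00 CPM with Ti (n = 3 per group), a log2 fold change of 0.87 ± 0.11, and Mt1 had 0.42 ± 0.10. Slc11a1, a divalent metal transporter of the phagosome, had 1.67 ± 0.28, and Lcn2, which binds bacterial siderophores, went from 10, 0 and 2 counts in the control libraries to 29, 28 and 269 with Ti, a log2 fold change of 4.90 ± 1.33 that was 3.16 without Ti replicate 3, 2.94 without both libraries numbered 3 and 6.42 without control replicate 1.

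Osteoclast genes had a median log2 fold change of 0.41, with 16 of 19 higher (camera adjusted p = 0.00431; adjusted p = 0.278 with an estimated correlation). Adjusted over the list alone 1 rose, the tyrosine kinase gene Src, by 2.06 ± 0.32, and 0 passed over all genes tested. Atp6v0d2, a proton pump subunit used in osteoclast fusion, had 1.67 ± 0.43, Jdp2 0.41 ± 0.11 and Acp5, the tartrate-resistant acid phosphatase, 1.29 ± 0.93, and 0.83 without control replicate 3, and none of these passed. Acp5 was low in the libraries numbered 3 of both groups. It stood at 8.54, 9.85 and 1.58 CPM in control replicates 1, 2 and 3 and at 23.7, 22.4 and 2.93 CPM in the Ti ones. Its unadjusted edgeR p was 0.211 without the replicate block and 0.00285 with it (adjusted over all genes 0.361 with the block). Without Ti replicate 1 the camera call was lost (adjusted p = 0.119). Extracellular matrix proteases and inhibitors had a median of 0.49, with 8 of 11 higher (camera adjusted p = 0.00299; adjusted p = 0.278 with an estimated correlation). Among the members that rose when adjusted over the list alone were Timp1 by 3.23 ± 0.62, Mmp12 by 2.05 ± 0.50 and Plaur by 1.17 ± 0.30, and 0 passed over all genes tested. The median was 0.29 without control replicate 2, 0.90 without control replicate 3 and 0.032 without Ti replicate 3. It was 1.16 with no filter on low counts, 0.21 with a stricter filter and 0.31 with unrescaled values. The gelatinase gene Mmp9 was not tested because its counts were uneven, 3, 0 and 0 in the control libraries and 254, 2 and 275 in Ti replicates 1, 2 and 3, and the filter removed it.

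Interferon-stimulated genes, 27 of 29 higher with a median log2 fold change of 0.46 (camera adjusted p = 0.00981; adjusted p = 0.779 with an estimated correlation), rested on 1 library. Without Ti replicate 3 the median was -0.18 (camera adjusted p = 0.198), without Ti replicate 1 or 2 it was 0.76, without control replicate 2 the call was lost (camera adjusted p = 0.126), and no member passed over all genes or adjusted over the list alone. Zbp1, a nucleic acid sensor, stood at 9.06, 9.83 and 34.7 CPM in Ti replicates 1, 2 and 3 and at 4.49 to 6.78 CPM in control. Ifit1, whose groups overlapped, stood at 353, 283 and 382 counts in the control libraries and at 375, 374 and 1285 in Ti replicates 1, 2 and 3. Gbp3 had a log2 fold change of 1.35 ± 0.57 and Ifi204 of 1.53 ± 0.68, and 0.38 without Ti replicate 3.

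4 further lists passed camera. Immediate early genes had a median of 0.18, with 14 of 20 higher (adjusted p = 0.0309; adjusted p = 0.708 with an estimated correlation); adjusted over the list alone Fosl1 rose by 1.19 ± 0.19, Myc by 1.67 ± 0.28 and Phlda1 by 1.68 ± 0.33, 3 members in all, and 0 over all genes. The median of that list was 0.071 with the replicate number as a block and 0.10 without on/off transcripts. It was -0.072 without Ti replicate 1 and 0.045 without control replicate 3, where its call was lost (camera adjusted p = 0.833 and 0.321), and 0.30 and 0.32 without Ti replicates 2 and 3; with unrescaled values the call was also lost (camera adjusted p = 0.0611) and the median was 0.096. Alternative activation genes, of which 6 of 17 were measured, had a median of 0.48 (camera adjusted p = 0.0119; adjusted p = 0.235 with an estimated correlation), and 1 of them, Myc, which the immediate early list also holds, rose adjusted over the list alone. This call was lost without Ti replicate 3 (camera adjusted p = 0.0731), with no filter on low counts (0.231) and with unrescaled values (0.134). The unfolded protein and amino acid stress response had a median of 0.16, with 22 of 27 higher (camera adjusted p = 0.00415; adjusted p = 0.558 with an estimated correlation), 0 members passed either adjustment, and Creld2 and Pdia4 had 0.39 ± 0.11 and 0.35 ± 0.13. Without Ti replicate 3 its median was 0.019 and the call was lost (camera adjusted p = 0.267); it was 0.35 without control replicate 3 and 0.27 and 0.30 without Ti replicates 1 and 2. Oxidative phosphorylation genes were lower by a small margin, 22 of 27 with a median of -0.10 (camera adjusted p = 0.0497; adjusted p = 0.708 with an estimated correlation), and 0 members passed either adjustment. Atp5c1 had -0.75 ± 0.45, and -0.14 without control replicate 1. Sdhc had -0.39 ± 0.25, and -0.15 without Ti replicate 1. That call was lost when control replicate 1, control replicate 2, Ti replicate 1 or Ti replicate 3 was left out (camera adjusted p = 0.150, 0.464, 0.267 and 0.198), and the median was -0.056 without control replicate 2 and -0.16 without control replicate 3. It was also lost with a stricter filter, DESeq2's size factors, unrescaled values or on/off transcripts left out (camera adjusted p = 0.0552 to 0.0820).

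The other lists did not pass. Cell cycle genes had a median log2 fold change of -0.08, with 26 of 36 lower (camera adjusted p = 0.0608; adjusted p = 0.708 with an estimated correlation); Cdc6 had -0.57 ± 0.20. This list passed camera with the replicate number as a block (adjusted p = 0.0324; adjusted p = 0.446 with an estimated correlation), with no filter on low counts (0.0316), without on/off transcripts (0.0467) and without control replicate 3, Ti replicate 1 or Ti replicate 2 (0.0186, 0.0174 and 0.00623). Its median was -0.012 without Ti replicate 3 and -0.027 without control replicate 2. Autophagy genes had a median of -0.10 (camera adjusted p = 0.141), and adjusted over the list alone 1 of 25 fell, the autophagy receptor gene Sqstm1, from 212 ± 31.1 to 92.1 ± 24.1 CPM (n = 3 per group), a log2 fold change of -1.20 ± 0.21. Apoptosis and p53 targets had a median of -0.07 (camera adjusted p = 0.318), and adjusted over the list alone the death receptor gene Fas rose by 1.35 ± 0.21 and Trp53inp1 fell by 1.20 ± 0.24. Cholesterol efflux and lipid loading genes had 0.28 (camera adjusted p = 0.173), with Cd63 rising by 0.51 ± 0.10 adjusted over the list alone. Toll-like receptor signalling genes had 0.07 (camera adjusted p = 0.890; Irak2 1.38 ± 0.36) and inflammasome and pyroptosis genes 0.05 (camera adjusted p = 0.890; P2rx7 -0.84 ± 0.21). Nlrp3, the inflammasome sensor, had 0.06 ± 1.21, since Ti replicate 3 stood at 1.52 CPM and Ti replicates 1 and 2 at 95.6 and 91.9 CPM. With on/off transcripts left out its log2 fold change was -0.26, so part of its values lay in such transcripts. NRF2 oxidative stress genes had -0.04 (camera adjusted p = 0.822), and their member Hmox1, the heme oxygenase, 0.62 ± 0.20.

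Lysosomal genes had a median log2 fold change of 0.00 (camera adjusted p = 0.960), heat shock genes 0.14 (camera adjusted p = 0.231), cholesterol synthesis and uptake -0.10 (camera adjusted p = 0.393), glycolysis and hypoxia 0.08 (camera adjusted p = 0.788) and antigen presentation 0.05 (camera adjusted p = 0.960). Macrophage lineage genes had 0.03 (camera adjusted p = 0.960), ribosomal proteins -0.05 (camera adjusted p = 0.130), mitochondrially encoded genes 0.06 (camera adjusted p = 0.960) and replication-dependent histones -0.02 (camera adjusted p = 0.318). In these lists 0 members passed over all genes or adjusted over the list alone. A median near 0 can hide members that move both ways. Fry's separate test for change in either direction passed for 5 lists without a camera call. They were apoptosis and p53 targets (adjusted p = 0.000343), cholesterol efflux (0.00546), lysosomal (0.00559), macrophage lineage (0.0245) and inflammasome genes (0.0369). At an unadjusted edgeR p under 0.05, 5 lysosomal genes were higher and 3 lower. Median, mean or test differed in sign for the inflammasome, lysosomal, NRF2, macrophage lineage, mitochondrially encoded and long non-coding RNA lists. Of the marker lists for other cell types, neutrophil and mast cell markers had 3 of 15 measured (median 1.08, camera adjusted p = 0.318), fibroblast 2 of 15 (median 0.50), osteoblast 2 of 10 (median 0.18), T and B cell 1 of 15 (0.37) and epithelial 0 of 12.

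Among non-coding genes 0 of 1540 tested passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 67, and DESeq2 called 9. The list of long non-coding RNAs and small RNA hosts had a median log2 fold change of 0.06 over 25 measured genes (camera adjusted p = 0.960), with 0 members past either adjustment. Its mean was -0.18. Malat1, the member with the smallest unadjusted edgeR p (0.0363), was very uneven. It stood at 509, 220 and 16079 CPM in control replicates 1, 2 and 3 and at 220, 225 and 318 CPM in the Ti ones. Over all 15376 genes, 1039 had an unadjusted p under 0.05 in edgeR, 526 higher and 513 lower.

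**Figure D3:**
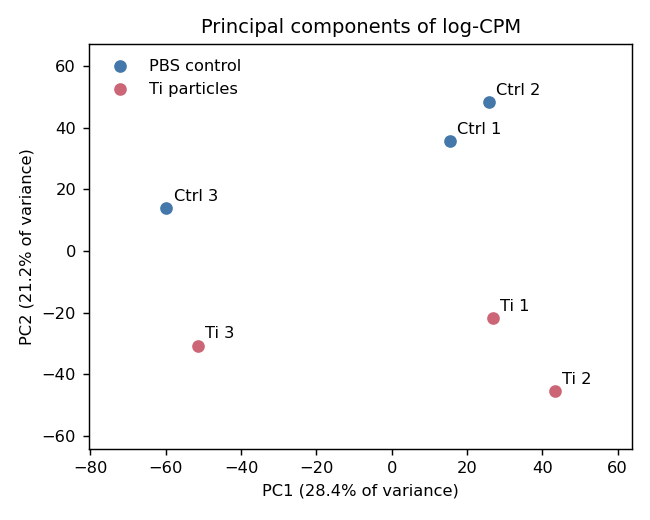
First and second principal components of log-CPM over the tested genes, each point one library, PBS control in blue and Ti particles in red. The first component (28.4% of the variance) parts the libraries numbered 3 from the others, and the second (21.2%) parts the groups.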

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

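The splits of the assembled transcripts were planned before their result was seen; the other tests in this part were chosen after it. No gene comparison used the assembled transcripts. The most abundant assembled transcript of each library took 28.1% of the deposited total in Ti replicate 1. The share was 7.36% to 7.47% in the control libraries and 9.09% and 6.53% in Ti replicates 2 and 3. Whether it was the same transcript in each library was not checked. The assembled transcript TCONS_00233970 was at 389, 198 and 281 deposited counts in control and at 54084, 38455 and 58477 with Ti, a log2 fold change of 7.58 (edgeR adjusted p = 0.0110). Of 31274 assembled transcripts tested 2 passed in edgeR, 1 higher and 1 lower, and DESeq2 called 646; 3 of the 10 splits of the 6 libraries gave as many, the highest other split 4, and 10 splits are too few for a share under 0.05.

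Mrps18c and Inpp5b were called although their difference lay in transcripts at or near 0 in one whole group. Transcripts that switch on and off from library to library were common: 639 transcripts in 560 genes were on in one library and off in another, 553 of them within a group. Of the 34 that were on in 3 libraries and off in 3, 6 followed the treatment, and the highest other split had 7, so the assignment of reads to transcripts may have produced such calls without a treatment effect. Among the 4 splits that part all 3 same-numbered pairs, the treatment split had 6 and the others 3, 2 and 5. So few splits cannot decide. Without these transcripts the log2 fold change was 0.026 for Inpp5b, from -2.64 ± 0.15, and 3.96 for Mrps18c, from 7.08 ± 0.21; they are chosen by the change itself, so this shows where the difference lies and not its cause. A switch between annotated isoforms is not seen, since no other annotated transcript of Inpp5b gained what ENSMUST00000184454 lost. The annotated transcripts of Mrps18c together were at 14, 8 and 8 counts in control and at 1234, 1202 and 1212 with Ti. Assembled transcripts have no gene or position and are not in these sums, so a shift of reads between them and annotated transcripts stays open. The reads were not analysed here.

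The chemokine list was higher with Ti particles, and 3 technical explanations were weighed. A trend with GC content, length or expression level is argued against by a mean log2 fold change of 1.18 after the trends were removed, from 1.25 (12 of 13 members had values), and transcripts that switch on and off, for the 8 members that reached 20 CPM in a library, by 0 such transcripts in them. RNA from neutrophils or mast cells in the Ti libraries is argued against for the 9 members at 5 CPM or more with Ti, since the 15 markers together rose by 0.034 times the median rise of these members in CPM. It stays open for the 4 members below 5 CPM, such as Ccl7 (there the ratio was 4.22), where the test could not decide. The 3 measured markers had a median log2 fold change of 1.08, which ranged from 0.52 to 1.38 with libraries left out. In each of them the groups overlapped. Hdc averaged 0.861 CPM in control and 1.92 CPM with Ti, from 0.987, 0.804 and 3.97 CPM in Ti replicates 1, 2 and 3. The 15 markers together rose by 1.54 ± 0.89 CPM (SE), too uneven to tell. A response of the macrophages to the treatment remains as a hypothesis for the 8 members; contaminants carried by the particles were not tested.

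The number of genes past the threshold differed by tool, 4 in edgeR and 292 in DESeq2. In edgeR 3 of the 10 splits gave as many genes as the treatment split, with 7 in the highest other split, control replicates 1 and 2 with Ti replicate 2 against the rest. In DESeq2 1 of the 10 gave as many, the treatment split itself, with 185 in the highest other; for lists in camera it was 1 of 10, with 13 lists in the treatment split and 12 in the highest other (NF-kB targets had an unadjusted camera p of 4.36e-11 in the treatment split and of 1.81e-05, 0.000270 and 0.000354 in 3 mixed ones), and for non-coding genes 10 of 10, which says nothing since the treatment split had 0 (the highest other had 3). Among the 4 splits that part all 3 same-numbered pairs, the treatment split gave 4 genes, 13 lists and 292 DESeq2 genes, and the others at most 3, 10 and 62. With 10 splits no share can be under 0.05, and on simulated counts for Ti against control over 15376 genes 39.3% of the DESeq2 calls and 10.8% of the edgeR calls were false.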

How the results depend on the processing

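Values summed without rescaling, robust dispersions, leaving out both libraries numbered 3, DESeq2 with the block and leaving out on/off transcripts were chosen after seeing the data; the cause of a change was not tested unless named. Against 2 genes higher, 2 lower, 0 non-coding and 13 lists, DESeq2 gave 163, 129 and 9, voom with quality weights 5, 5 and 1, DESeq2 with the replicate block 262, 167 and 12, and the edgeR replicate block 0 higher and 0 lower, with 14 lists. Leaving out on/off transcripts gave 0 higher and 0 lower, no filter 1 lower, and unrescaled values 1 non-coding gene. Leaving out one library gave 1 to 8 higher, 0 to 7 lower, 0 to 1 non-coding and 9 to 17 lists, and leaving out both libraries numbered 3 gave 0, 0 and 8 lists. With an estimated correlation 0 lists passed. With the block 0 lists passed fry's test for change in one direction, against 3. In camera the block changed no other list call than that of the cell cycle list. Pseudocounts and TPM were not run, since they apply to FPKM; median-ratio scaling is the DESeq2 size factors. DESeq2, voom and robust dispersions do not enter the list test, so they give no other list counts. Of the named genes Nlrp3 changed sign, with a log2 fold change of -0.21 by voom, -0.33 with the replicate block in edgeR and in DESeq2, -0.26 without on/off transcripts and -0.37 to 1.12 when libraries were left out, and Inpp5b had 0.026 without on/off transcripts, on which its call rested. Of the called lists 2 changed the sign of their median when libraries were left out, interferon-stimulated genes (-0.18 to 0.76) and immediate early genes (-0.072 to 0.32).

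The other medians that changed sign belong to lists that did not pass with all libraries. With a library left out some of them passed camera: ribosomal proteins without control replicate 3 or Ti replicate 2 (adjusted p = 0.00628 and 0.000137), cholesterol synthesis without Ti replicate 3 (0.00665), cholesterol efflux, glycolysis and histones without control replicate 3 (0.0186, 0.0166 and 0.0166), and histones and mitochondrially encoded genes without Ti replicate 2 (0.0232 and 0.0253). Lysosomal genes had -0.0091 with no filter, -0.028 with the replicate block, -0.021 unrescaled, -0.019 without on/off transcripts and -0.15 to 0.10 when libraries were left out. Without on/off transcripts the inflammasome list had -0.032 and the macrophage lineage list -0.045; with the replicate block the macrophage lineage list had -0.029 and antigen presentation -0.011. When libraries were left out, the ranges were -0.042 to 0.12 for Toll-like receptor signalling, -0.034 to 0.18 for the inflammasome, -0.094 to 0.0011 for NRF2 genes, -0.29 to 0.10 for cholesterol synthesis, -0.020 to 0.44 for cholesterol efflux, -0.10 to 0.26 for glycolysis, -0.19 to 0.20 for antigen presentation, -0.15 to 0.14 for macrophage lineage genes, -0.15 to 0.0048 for ribosomal proteins, -0.17 to 0.23 for mitochondrially encoded genes, -0.15 to 0.088 for histones and -0.16 to 0.16 for long non-coding RNAs. Depth limits Il6; Mmp9 was removed by the filter because its counts were uneven among the Ti libraries.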

Other observations

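The genes in this part were chosen after their values were seen. Several genes outside the fixed lists were higher in every Ti library than in every control library and were called by DESeq2 but not by edgeR, whose adjusted p for them ranged from 0.101 to 0.228. Acod1, which makes itaconate in activated macrophages, averaged 11.96 ± 1.18 CPM in control and 82.1 ± 40.3 CPM with Ti (SD, n = 3), a log2 fold change of 2.78 ± 0.36 (edgeR adjusted p = 0.134). Zc3h12a, an RNase that degrades cytokine mRNA, had 1.72 ± 0.18 (edgeR adjusted p = 0.101), and Dusp5, a phosphatase of ERK, 1.98 ± 0.26. The integrin gene Itga5 averaged 171 ± 2.44 and 297 ± 32.6 CPM, a log2 fold change of 0.80 ± 0.10. Rgs16, a regulator of G protein signalling, had 2.62 ± 0.41, the chemokine receptor gene Ccr1 2.90 ± 0.35 and the adenosine receptor gene Adora2b 1.20 ± 0.20 (edgeR adjusted p = 0.228).

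Among genes that DESeq2 called lower, Flcn, which encodes folliculin, averaged 40.9 ± 6.88 CPM in control and 11.96 ± 2.55 CPM with Ti, a log2 fold change of -1.78 ± 0.22. Atp13a2, a lysosomal polyamine transporter, had -0.89 ± 0.12, and Lgmn, a lysosomal protease, -0.55 ± 0.09. None of these genes passed in edgeR over all genes tested. The fixed lysosomal list, which holds neither Atp13a2 nor Lgmn, did not fall as a group: 17 members were higher and 15 lower.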
